A study of Mus musculus with 4 samples.

How the data were processed

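Mouse skin RNA was measured on NimbleGen expression arrays with 1-colour Cy3 labelling, 1 array for each of 4 groups: Control, ATRA, ATRA+NIC and NIC. Per the labels, back skin of male BALB/c mice was treated for 5 days, RNA was extracted with Trizol and its quantity and integrity were checked by NanoDrop and gel. Mice of all 4 groups have the same age in the labels. The labels speak of RNA from 4 mouse skins. They do not say whether RNA of several mice was pooled for an array, and the concentration of nicotinamide is not given. The title of the series names epidermis and the sample labels name skin. The layout is a 2 by 2 factorial, ATRA yes or no and NIC yes or no.

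The authors deposited, for each array, a gene-level intensity per target on the linear scale, named as RMA values in the file names, and these deposited intensities were used. RMA adjusts for background, normalises between arrays and summarises the probes of a target, here 3 probes for 44155 of 44170 targets. Software versions and settings are not given in the sources used here. The deposited value table of the series holds the same intensities for 24323 targets, each at 50 or above on all 4 arrays. Its values matched the per-array intensities with a largest relative difference of 9.0e-07, and the other 19847 targets were below 50 on at least 1 array. The per-array intensities were the main source since that table leaves out genes that are low on 1 array. A workbook of the authors was not used here because its columns carry no group names, and 4 further per-array columns were not used here.

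Intensities were put on the log2 scale with no further normalization. Target names were brought to current symbols by gene ID for 39057 targets, 2829 kept the symbol of the array and 2284 had none. Targets of a symbol were averaged, which gave 24171 symbols, and 14552 were kept whose value was at or above the array's median over all targets on at least 1 array. Signal over background limits dim genes: the 5000 random control probes read 34.2 on Control, 34.8 on ATRA, 36.3 on ATRA+NIC and 34.0 on NIC, and 60.2%, 59.5%, 58.7% and 60.0% of targets read at least 2 times that. Between arrays the log2 values of kept symbols correlated with Pearson r from 0.913 to 0.951.

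Differences were ATRA minus Control, NIC minus Control, ATRA+NIC minus Control, ATRA+NIC minus ATRA and ATRA+NIC minus NIC, with counts of symbols at least 2-fold apart. With 1 array per group these have no test. An effect was also read in both backgrounds, as symbols at least 2-fold the same way in a pair of differences that share no array. The mean of both ATRA differences (ATRA axis), the mean of both NIC differences (NIC axis) and the interaction axis, 0.5 times the difference of both ATRA differences, carry equal array noise. An additive limma fit (lmFit and eBayes, terms ATRA and NIC, 1 residual degree of freedom) gave p-values, adjusted by Benjamini-Hochberg over the kept symbols, and also over each list alone. The adjustment over a list alone does not correct for the number of lists, some of which share genes. For the brightest decile of symbols 95% of absolute interaction values, scaled to a difference of 2 arrays, lay within 0.75 log2, and for the dimmest decile within 2.18. Olfactory and vomeronasal receptors, 920 symbols that skin should not express, had a standard deviation between 0.77 and 0.89 in the differences of array pairs.

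Before the data were examined, 33 gene lists were fixed: retinoid response and metabolism, EGF-family ligands, cornified envelope structural proteins, SPRR and LCE3 stress-induced envelope precursors, transglutaminases and barrier proteases, ceramide and barrier lipid synthesis, cholesterol and fatty acid synthesis, tight and adherens junctions and desmosomes, aquaporins and hydration, hyperproliferation keratins and alarmins, basal keratinocyte genes, cell cycle, inflammatory cytokines and chemokines, NAD and nicotinamide metabolism, oxidative stress and NRF2 targets, interferon response, immediate early genes, heat shock and unfolded protein response, extracellular matrix, and markers of melanocytes, hair shaft and inner root sheath, hair follicle stem and bulge cells, sebocytes, adipocytes, skeletal muscle, fibroblasts, endothelium, macrophages and dendritic cells, neutrophils, T, NK and B cells, mast cells, red blood cells, and nerve and Schwann cells. A list's median was set against 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile describes these arrays only. For lists of unrelated genes 1.65 of 33 would lie outside the middle 95% by chance. Genes of a list can move together on an array, so more can lie outside with no treatment effect. For the ATRA axis 12 lay above and 3 below, for the NIC axis 3 above and 8 below, and for the interaction axis 5 above and 4 below. Sets of ATRA-responsive symbols were compared with 1000 random sets each.

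Named genes were chosen by a rule fixed at the same time: the 12 highest and 12 lowest for ATRA by the smaller of both differences, at least 2-fold in both; the 8 highest and 8 lowest for NIC by the same rule; the 8 highest and 8 lowest of ATRA+NIC minus ATRA and of NIC minus Control; up to 4 members of each list with the largest difference in the comparison described; and 22 genes named whatever their value, among them Cyp26a1, Crabp2, Hbegf, Krt10, Flg, Lor, Ivl, Aqp3, Nampt and Sirt1. Unnamed, predicted and receptor symbols were counted and not named. Not every gene that qualified is printed below, and of the 22 genes Dhrs3 and Krt16 are not.

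The steps were tested on simulated data with normal noise, independent between symbols and set by brightness decile from the interaction axis. The rule of both backgrounds found 16.4% of 2-fold, 80.6% of 4-fold and 100% of 8-fold symbols and called 1.07% of unchanged ones. The limma fit found 0, 43.3% and 95.5% and called 0.0836% of unchanged ones. Of simulated lists with no effect, 4% lay outside the middle 95%. Their symbols were picked at random with independent noise, so this rate does not hold for lists whose genes move together.

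Alternatives were each array centred on its median, cyclic loess between arrays, no filter on dim genes, only symbols at or above percentile 75 of brightness, the brightest target of a symbol, the deposited value table, 1.5-fold and 3-fold limits, an intensity trend in eBayes and unadjusted p, and, chosen after the data were seen, counts without hair and Krtap genes. With 1 array per group no array could be left out. Tools were Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, R 4.3.3 and limma 3.58.1.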

Results

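Gene expression was measured in back skin of male BALB/c mice treated with creams for 5 days. The 4 groups received an oil/water cream (Control), a cream with 0.1% all-trans retinoic acid (ATRA), the ATRA cream together with a nicotinamide cream (ATRA+NIC), or the nicotinamide cream alone (NIC). ATRA is the acid form of vitamin A, which acts through nuclear retinoic acid receptors, and nicotinamide is the amide form of vitamin B3 and a precursor of NAD. Whether an array holds RNA of 1 mouse or a pool is not stated. Each group was measured on 1 array, so no difference between groups can be set against a spread between replicates, and the number of arrays limits the precision of every value. Values are intensities that the authors normalised with RMA. The median intensity over all targets was 105 on the Control array, 102 on ATRA, 102 on ATRA+NIC and 103 on NIC, and the random control probes read 34.2, 34.8, 36.3 and 34.0 on the same arrays. All differences are on the log2 scale, and 14552 gene symbols with at least 1 array at or above its median were compared. Gene positions are on mouse build MM9.

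The series title names genes of the epidermal barrier in skin treated with ATRA and nicotinamide, and the ATRA creams were compared with their matching creams without ATRA. ATRA minus Control and ATRA+NIC minus NIC share no array. Values given in pairs for ATRA are in that order. Hair shaft and inner root sheath genes, whose products build the hair fibre and its sheath, were lower on both ATRA arrays. All 34 measured members of this list were at least 2-fold lower in both differences, with medians of -3.56 and -3.84, and 0% of 10000 random lists matched on brightness had medians as low. Krt34, a hair shaft keratin (chromosome 11, 99898701 to 99902846), read 7193 on Control, 71.2 on ATRA, 630.1 on ATRA+NIC and 21543 on NIC, differences of -6.66 and -5.10. Krt83, another hair shaft keratin, differed by -5.01 and -4.95, Krt33a by -5.30 and -4.99 and Krtap3-3, a keratin-associated protein of the hair shaft, by -6.16 and -5.49.

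The hair genes outside the Krtap family were also lower. Padi3, a peptidylarginine deiminase of the hair follicle (chromosome 4, 140341283 to 140359937), differed by -3.20 and -3.69 and its substrate trichohyalin, Tchh, by -2.26 and -2.05. The Krtap family as a whole, 39 symbols, had medians of -4.63 and -4.55. The 12 named genes that were lowest by the smaller of both differences were all hair genes: Krtap2-4 (-5.94 and -6.05), Krtap4-16 (-5.40 and -5.79), Krtap28-13 (-5.36 and -5.85), Krtap16-3 (-5.32 and -5.43), Krtap6-1 (-6.07 and -5.19), Krtap3-2 (-5.15 and -5.31), Krtap4-7 (-5.05 and -6.15), Krtap22-2 (-6.62 and -4.99) and Krtap3-1 (-5.66 and -4.97), besides Krtap3-3, Krt34 and Krt33a. On the ATRA array 14 of the 39 Krtap symbols read under 2 times the random probes, and on ATRA+NIC 4 did, so their folds are limited by the array's background. Krtap genes have similar sequences, and a probe for one may have read another, so single Krtap values are less certain than the family's.

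In an additive limma fit of ATRA and NIC over all 4 arrays, 88 symbols fell and 2 rose with ATRA at a Benjamini-Hochberg adjusted p under 0.05, with adjusted p from 0.00962 to 0.0490. Of the 88 that fell, 41 were hair list or Krtap genes, 42 were unnamed or predicted genes and 5 were other named genes. Whether the 42 include hair genes was not examined, so the 41 may understate the hair share. Krt34 fell by 5.88 (SE 0.45, limma adjusted p = 0.0107), Krt83 fell by 4.98 (SE 0.29, limma adjusted p = 0.00962), Padi3 fell by 3.44 (SE 0.31, limma adjusted p = 0.0187) and Car6, a secreted carbonic anhydrase, fell by 4.51 (SE 0.29, limma adjusted p = 0.00962). Car6 read 58.7 on ATRA, under 2 times the random probes. Of the 34 hair list members, 19 fell over all genes and 34 fell when adjusted over the list alone. Here and below, adjustment over a list alone does not correct for the number of lists. The fit has 1 residual degree of freedom, taken from the interaction, so its p-values hold only where ATRA and NIC act additively. With each array centred on its median, with cyclic loess, or with the brightest target of each symbol, 0 symbols rose with ATRA, while 75, 68 and 66 fell. Other alternatives gave more, with 185 that rose and 307 that fell with an intensity trend, 29 and 134 at or above percentile 75 of brightness, 27 and 145 in the deposited value table and 8 and 114 with no filter on dim genes.

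Genes of the stressed and cornifying epidermis were higher on both ATRA arrays. Of 19 measured SPRR and LCE3 genes, small envelope precursors induced when the barrier is stressed, 8 were at least 2-fold higher in ATRA minus Control and 12 in ATRA+NIC minus NIC, with 7 in both and list medians of 0.68 and 1.79 (percentile 100 of random lists for their mean). Lce3c (chromosome 3, 92749137 to 92749507) read 1345 on Control and 7194 on ATRA, and 1095 on NIC and 6969 on ATRA+NIC, and rose by 2.54 (SE 0.30, limma adjusted p = 0.0483). Tmprss11b, a membrane serine protease of squamous epithelia (chromosome 5, 87088549 to 87105323), rose by 3.06 (SE 0.35, limma adjusted p = 0.0445), and its paralog Tmprss11g differed by 2.34 and 2.77. Tmprss11b read 67.2 on Control and 47.8 on NIC, and Tmprss11g 40.8 and 38.1, under 2 times the random probes, so the sizes of these differences are limited by the background. Among the other members of the list Lce3f differed by 2.29 and 3.66, Lce3a by 2.07 and 3.84, Lce3b by 1.71 and 4.35 and Sprr2g by 1.91 and 4.25. Over all genes 1 member of the list rose, and adjusted over the list alone 10 rose and 1 fell, the latter Sprr4, a gene picked out after its values were seen, at -1.36 and -1.57.

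Hyperproliferation keratins and alarmins, the genes of a wounded or inflamed epidermis, were higher on both ATRA arrays, with list medians of 0.37 and 1.27. Of 21 measured members 6 were at least 2-fold higher in both differences, 0 rose over all genes and 8 rose when adjusted over the list alone. S100a8 and S100a9, the subunits of calprotectin, differed by 1.72 and 3.44 and by 1.93 and 3.41. Krt6a, a keratin of wounded epidermis, differed by 1.26 and 1.89, the antimicrobial peptide gene Defb3 by 2.11 and 5.42 and the protease inhibitor gene Slpi by 1.81 and 2.17. S100a8 and S100a9 are also held by the neutrophil list, whose medians were 1.60 and 0.86, and other neutrophil genes such as Csf3r (1.47 and 1.29) and Retnlg (1.88 and 0.84) were higher, though Csf3r read 48.9 on Control and 49.8 on NIC, under 2 times the random probes. In the neutrophil list 0 of 12 rose over all genes and 6 rose when adjusted over the list alone.

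Cytokine, matrix, mast cell, macrophage and endothelial genes were higher as groups on the ATRA arrays, and T, NK and B cell genes were not in both differences, with medians of 0.26 and -0.049. The list of inflammatory cytokines and chemokines had medians of 0.30 and 0.52, with Il33, an alarm cytokine of epithelial cells, at 2.19 and 2.90, Il19, which read 61.7 on Control, at 2.65 and 1.26, the neutrophil attractant Cxcl1 at 1.08 and 2.41 and Il1b at 1.60 and 1.45. The Control reading of Il19 is under 2 times the random probes, which limits its ATRA minus Control value. Extracellular matrix genes had medians of 0.42 and 0.29, with the protease inhibitor gene Timp1 at 2.32 and 2.61 and the matrix proteases Mmp3 at 2.15 and 1.49 and Mmp9 at 1.90 and 1.31. Adjusted over each list alone, 5 cytokine and 3 matrix genes rose, and over all genes 0 and 0. Mast cell genes had medians of 0.60 and 0.72 with Mcpt4, a mast cell protease, at 0.95 and 1.17, macrophage and dendritic cell genes 0.33 and 0.46 with Fcgr1 at 1.86 and 0.99, and endothelial genes 0.52 and 0.50 with Ptprb at 0.93 and 1.34. Of these 0 of 8 mast cell, 0 of 22 macrophage and dendritic cell and 0 of 16 endothelial genes rose with ATRA, over all genes or adjusted over the list alone. With an intensity trend in the fit, 3, 2 and 1 genes of these lists rose over all genes.

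Genes of mature barrier formation went both ways. Cornified envelope genes had medians of -0.16 and 0.18, where 5 members, all LCE3 genes, rose and 4 fell when adjusted over the list alone, and 1 rose over all genes. The 4 that fell were Tchh, also in the hair list, Sprr4, also in the SPRR and LCE3 list, Krt77 and Lce1m. Krt77, a keratin of the upper epidermis and sweat duct, fell by 2.77 (limma adjusted p = 0.00687 adjusted over the list alone) and Lce1m, a late envelope gene, fell by 1.91 (limma adjusted p = 0.0154 adjusted over the list alone). The main structural genes were less than 2-fold apart in both differences, with Flg (filaggrin) at -0.51 and -0.12, Lor (loricrin) at -0.39 and -0.0017, Krt1 at -0.28 and 0.18 and Krt10 at -0.071 and 0.91, while Ivl (involucrin) was at -0.38 and -1.27. Transglutaminase and barrier protease genes had medians of 0.16 and 0.52 against a negative mean in ATRA minus Control, with Klk10, a kallikrein protease, at 1.54 and 0.82 and Tgm1, the envelope crosslinking enzyme, at 0.36 and 0.43. Of 27 members 2, Padi1 and Padi3, fell when adjusted over the list alone. Over all genes 1 fell, Padi3, which is also in the hair list. Ceramide and barrier lipid genes had medians of 0.075 and 0.34, with Degs2, a ceramide desaturase, at 1.30 and 1.56 and Alox12b, a barrier lipoxygenase, at 0.82 and 1.25. Cholesterol and fatty acid synthesis genes had medians of 0.092 and 0.23.

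Genes of retinoid response and metabolism had medians of 0.23 and 0.31, at percentiles 95.6 and 99.2 of random lists, and 0 of 24 rose by either adjustment. Crabp2, a retinoic acid binding protein, differed by 0.55 and 0.59 and Cyp26b1, which degrades retinoic acid, by 0.33 and 0.19. The retinoid target genes Cyp26a1 and Rarb read 29.4 and 38.8 on the ATRA array, near the random probes at 34.8, so a difference was not detectable at this signal. Of EGF-family ligands, medians 0.65 and 0.36, Hbegf, a keratinocyte growth factor, differed by 0.93 and 1.05 and Epgn by 0.78 and 1.11, while Btc was at -1.51 and 0.35. Cell cycle genes had medians of 0.17 and -0.19, and Mki67, the proliferation marker, differed by 0.16 and -0.0100.

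Melanocyte genes were lower on both ATRA arrays, with medians of -0.78 and -2.06. Mlana differed by -1.66 and -3.39 and Tyr, the pigment enzyme tyrosinase, by -1.42 and -2.75, and 0 of 12 fell over all genes while 9 fell when adjusted over the list alone. Genes of hair follicle stem and bulge cells had medians of -0.29 and -0.78, with Sox9 at -0.76 and -1.61.

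**Figure D1:**
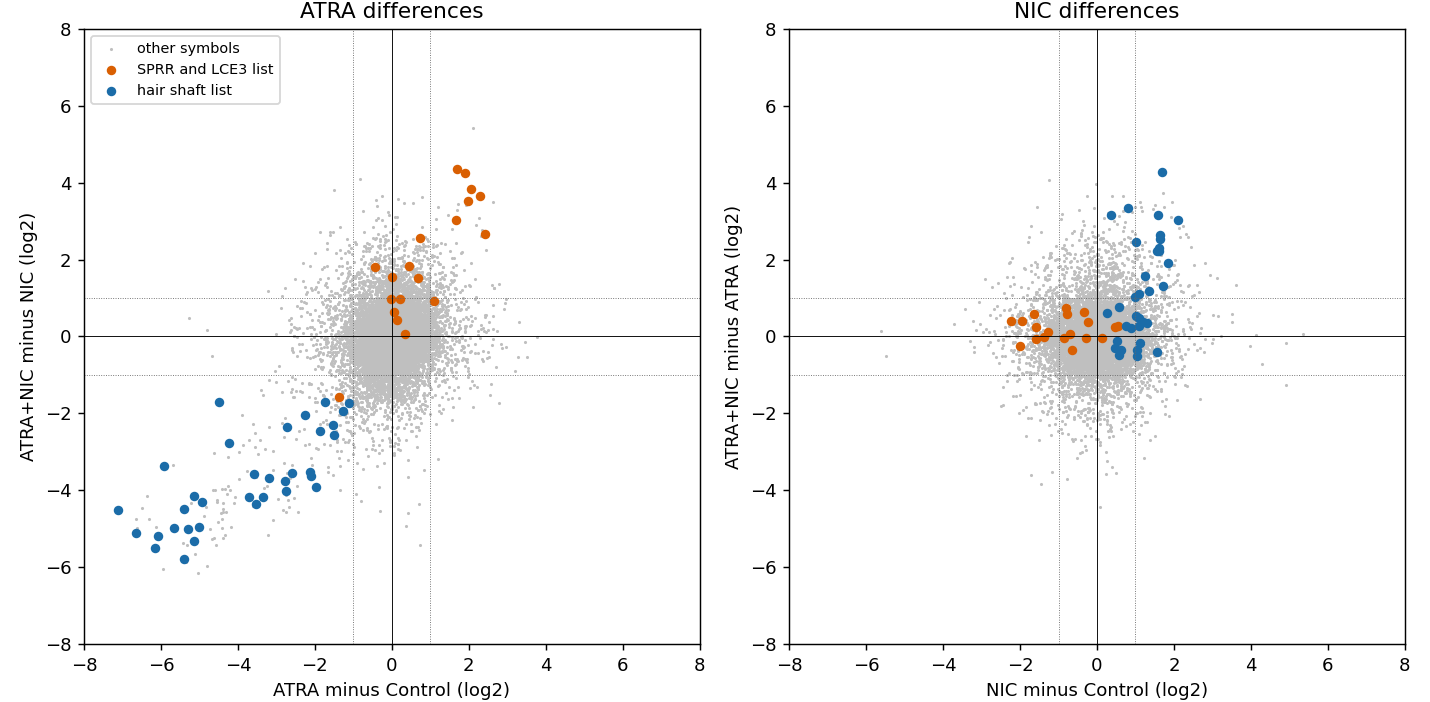
Each point is a gene symbol, with log2 differences in the 2 backgrounds on the axes: for ATRA, ATRA minus Control against ATRA+NIC minus NIC, and for NIC, NIC minus Control against ATRA+NIC minus ATRA. Hair list genes (blue) lie at low values on both ATRA axes, at a median of -3.56 on one and -3.84 on the other, and SPRR and LCE3 genes (orange) at medians of 0.68 and 1.79; dotted lines mark 2-fold.

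Over all symbols 598 were at least 2-fold higher and 797 lower in ATRA minus Control, and 1007 and 1104 in ATRA+NIC minus NIC. The same symbols passed in both differences 121 times for higher and 275 times for lower, against 41.4 and 60.5 for independent lists, and 39 and 94 passed in opposite directions. In simulated arrays the 14352 symbols that were given noise and no effect passed in both 75 and 78 times. Correlation of the differences across genes was r = 0.343, and genes are not independent replicates. Without hair and Krtap genes, an alternative chosen after seeing the data, 121 and 213 symbols remained. That count still holds unnamed and predicted symbols, which may include hair genes. At or above percentile 75 of brightness 27 symbols were higher and 130 lower in both. Without hair and Krtap genes 27 and 81 remained, and without unnamed and predicted symbols as well 25 and 27.

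The NIC cream was compared with the Control cream, and ATRA+NIC with ATRA, to read what nicotinamide changed in skin without and with ATRA. Values in pairs for NIC are in that order. The hair list was higher in both NIC differences, with medians of 1.10 and 0.90, at percentile 100 of random lists for their mean, and 26 of its 34 members above 0 in both. Krt34 differed by 1.58 and 3.15, Krt83 by 1.85 and 1.91 and Krtap7-1 by 1.68 and 4.27. In the limma fit 0 symbols rose and 0 fell with NIC at an adjusted p under 0.05 over all genes (smallest adjusted p 0.688, with 400 and 367 at an unadjusted p under 0.05), while 16 of the 34 hair genes rose when adjusted over the list alone. With an intensity trend in the limma fit, 93 symbols rose and 32 fell with NIC. That fit called 0.0206% of symbols in simulated arrays with no NIC effect. The simulated noise depended on brightness alone, as this fit assumes, so the low rate was built in. It does not bound the false calls of that fit on these arrays. With the fit restricted to symbols at or above percentile 75 of brightness, 27 symbols rose and 0 fell.

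Stress-induced envelope genes and alarmins were lower on the NIC array than on Control, and not lower to that extent on ATRA+NIC than on ATRA. SPRR and LCE3 genes had medians of -0.81 and 0.24, with Lce3a at -2.01 and -0.24, Lce3b at -2.23 and 0.41 and Sprr2b at -1.28 and 0.10. Hyperproliferation keratins and alarmins had medians of -0.57 and -0.030, with S100a8 at -1.72 and -0.0091, S100a9 at -1.51 and -0.030, Krt6b at -1.85 and 0.093 and Defb3 at -3.15 and 0.16. Macrophage and dendritic cell genes were lower in both, with medians of -0.46 and -0.35, among them the complement gene C1qc at -0.74 and -1.01 and Itgam, which read 54.6 on NIC, under 2 times the random probes, at -1.61 and -0.57, and neutrophil genes had medians of -0.45 and -0.56. T, NK and B cell genes had medians of -0.20 and -0.63, and inflammatory cytokines and chemokines were not lower, at 0.025 and 0.057. In the limma fit 0 of 19 SPRR and LCE3, 0 of 21 alarmin list, 0 of 22 macrophage and dendritic cell and 0 of 12 neutrophil genes fell with NIC, over all genes or adjusted over the list alone, and 0 of each list were at least 2-fold lower in both differences. With an intensity trend in the fit, 1, 3, 1 and 1 genes of these lists fell over all genes. Melanocyte genes had medians of 0.97 and -0.22, and red blood cell genes 0.48 and 0.37, with the haemoglobin gene Hbb-b1 at 0.82 and 0.37.

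Genes with a direct tie to nicotinamide moved little as a list, with NAD and nicotinamide metabolism at medians of 0.021 and 0.058. Sirt1, an NAD-dependent deacetylase, differed by 1.56 and 1.58 from 77.9 on Control and 87.2 on ATRA, Nnmt, which methylates nicotinamide, by 0.94 and 0.40, and Nampt, the rate-limiting enzyme of NAD salvage, by 0.23 and -0.028. EGF-family ligands had medians of 0.52 and 0.81, at percentiles 97.0 and 99.975 of random lists, with 4 of 7 members above 0 in both and 0 called by limma. Areg differed by 0.95 and 1.11, while Hbegf was lower in both, at -0.75 and -0.63, and Btc was at -0.88 and 0.99. Immediate early genes, induced within minutes of a stimulus, had medians of 0.29 and 0.31, with 8 of 20 members above 0 in both and 0 below 0 in both. Atf3 was at 2.48 and 1.05 and Nr4a1 at 0.84 and 0.44, while Jun was at -0.81 and 0.075 and Dusp1 at -0.49 and 0.56. Of barrier genes, ceramide and barrier lipid genes had medians of -0.21 and -0.036, tight and adherens junction and desmosome genes 0.15 and -0.055 and aquaporins and hydration genes -0.44 and 0.21, with Aqp3, a glycerol and water channel of keratinocytes, at -0.70 and 0.35, Cldn1 at 0.38 and -0.18, Sptlc1 at -0.094 and -0.044 and Ivl at 1.12 and 0.23.

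By the ranking rule the highest genes in both NIC differences were Il1f10, an interleukin-1 family cytokine, at 2.36 and 2.58, Krtap16-3 at 2.44 and 2.33, Galntl5 at 2.14 and 2.81, Krtap14 at 2.12 and 3.03, Krtap19-9b at 1.95 and 3.51, Krtap19-2 at 1.93 and 3.09, Ctnna2 at 2.80 and 1.90 and Car6 at 2.01 and 1.86. All 8 read under 2 times the random probes on ATRA, such as Il1f10 at 38.7 and Car6 at 58.7, and Galntl5 and Ctnna2 also did on Control, at 36.4 and 31.2, so their sizes and order are limited by the background. The lowest were dim, among them Tm4sf20 at -2.49 and -1.80 and Mt3, a metallothionein, at -2.19 and -1.55, whose brightest reading was 248. In NIC minus Control, 775 symbols were at least 2-fold higher and 780 lower, and 727 and 620 in ATRA+NIC minus ATRA. The same symbols passed in both 129 times for higher and 73 times for lower, with 64 and 81 in opposite directions, and simulated noise alone gave 72 and 80, so the count for lower was no larger than noise gives. Across genes the 2 NIC differences had r = 0.0458. The largest single differences were in genes bright on 1 array only, such as Prf1, the lymphocyte pore protein perforin, at 2419 on NIC and 80.7 on Control, and Cnksr3, at 9164 on Control and 185 on NIC.

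**Figure D2:**
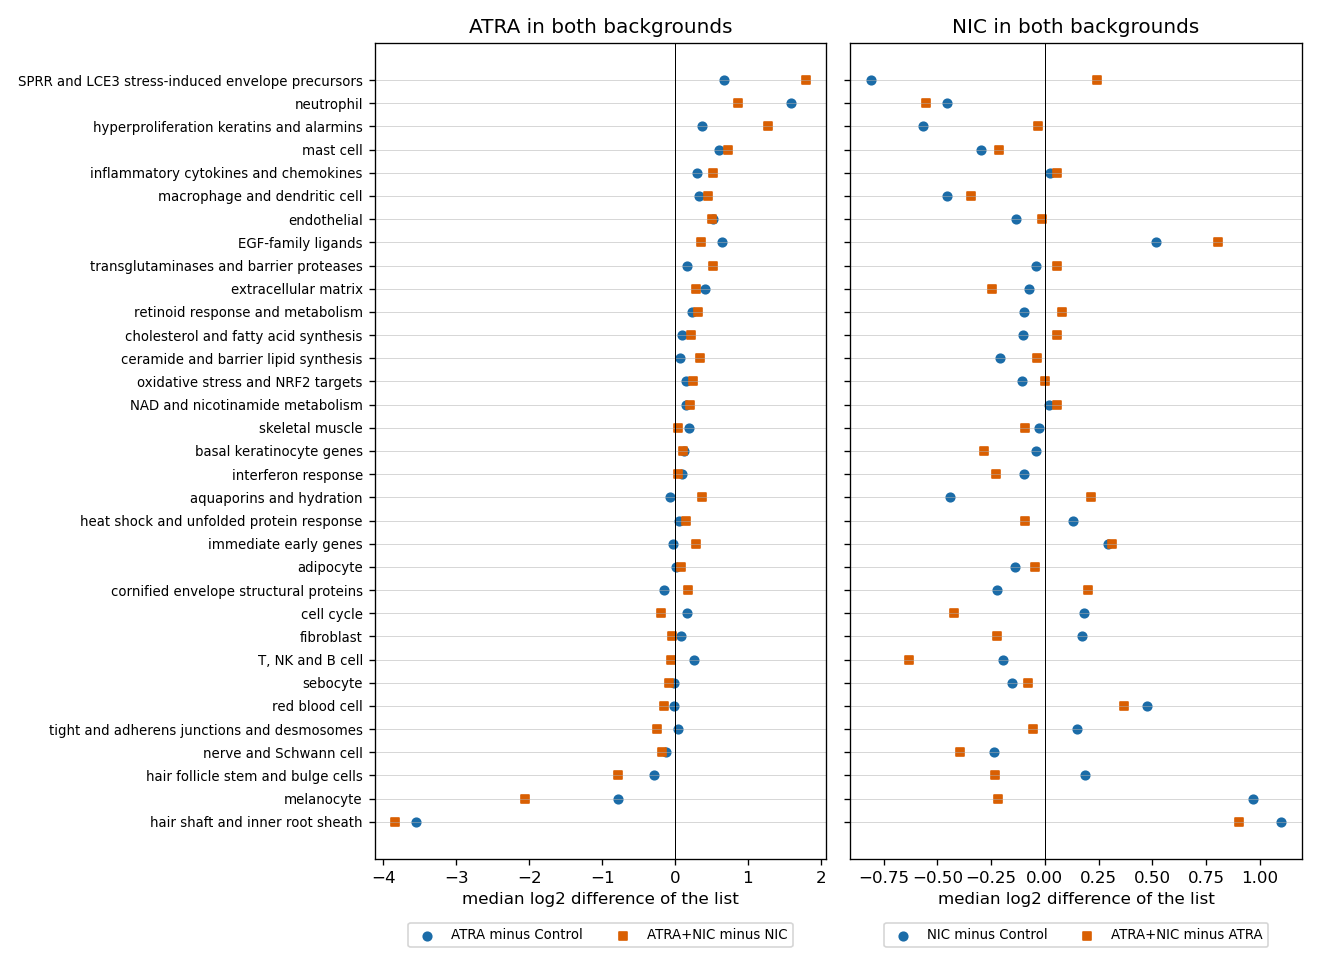
Medians of the 33 gene lists, on the log2 scale, for ATRA (left) and NIC (right) in both backgrounds, circles for ATRA minus Control or NIC minus Control and squares for ATRA+NIC minus NIC or ATRA+NIC minus ATRA. The hair list has the lowest medians for ATRA (-3.56 and -3.84) and the SPRR and LCE3 list one of the highest (0.68 and 1.79), and the melanocyte list lies at -0.78 and -2.06.

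ATRA+NIC was compared with ATRA to read what the added nicotinamide changed in ATRA-treated skin. Genes higher with ATRA shifted little with added nicotinamide: the 425 symbols at least 2-fold higher on the mean of both ATRA differences had a median of 0.096 in ATRA+NIC minus ATRA, against -0.085 to 0.064 for the middle 95% of random sets, and 230 of them were above 0. That median was -0.032 in the deposited value table and 0.0066 at or above percentile 75 of brightness, so its direction depends on the processing. The 561 symbols at least 2-fold lower had a median of 0.019, inside the range of random sets, -0.065 to 0.028, but 0.67 at or above percentile 75 of brightness. In NIC minus Control the 425 symbols had a median of -0.22, against -0.056 to 0.11 for random sets. There the 561 had a median of 0.65, against -0.032 to 0.090, and 0.48 without hair genes. The hair list was higher, at 0.90, with Krtap13-1 at 3.73 and Krt34 at 3.15, but was still at -2.58 in ATRA+NIC minus Control. Not all members were higher, with 26 of 34 above 0 in both NIC differences, and Krt28 at -0.50 and Dlx3 at -0.49. This rise was not particular to skin with ATRA: the Krtap family had medians of 1.59 in NIC minus Control and 1.58 in ATRA+NIC minus ATRA. Cell cycle genes were lower, with a median of -0.42 against 0.18 in NIC minus Control, and 0 of 33 fell with NIC in the limma fit over all genes or adjusted over the list alone. Among its lower members were Cdt1, a replication licensing factor, at -1.50, Mcm2, a replication helicase subunit, at -1.07 and Bub1b at -1.39. T, NK and B cell genes had a median of -0.63 and basal keratinocyte genes -0.28, against -0.20 and -0.040 in NIC minus Control, and among the largest single gene differences were Krtap7-1 at 4.27, Gata6 at 3.66, Hamp, which encodes the iron hormone hepcidin, at 3.65, and Septin10 at -4.43. Krtap7-1 at 51.4, Krtap13-1 at 43.3 and Gata6 at 23.3 on ATRA, and Septin10 at 66.3 on ATRA+NIC, read under 2 times the random probes, so these sizes and their order are limited by the background.

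ATRA+NIC was compared with Control for the combined treatment, where 846 symbols were at least 2-fold higher and 1018 lower. SPRR and LCE3 genes had a median of 0.73, alarmins 0.42, cytokines 0.38, hair genes -2.58 and melanocyte genes -1.24. Il33 was at 2.40, S100a8 at 1.72, Lce3c at 2.37, Cxcl1 at 2.39 and Krt83 at -3.11.

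**Figure D3:**
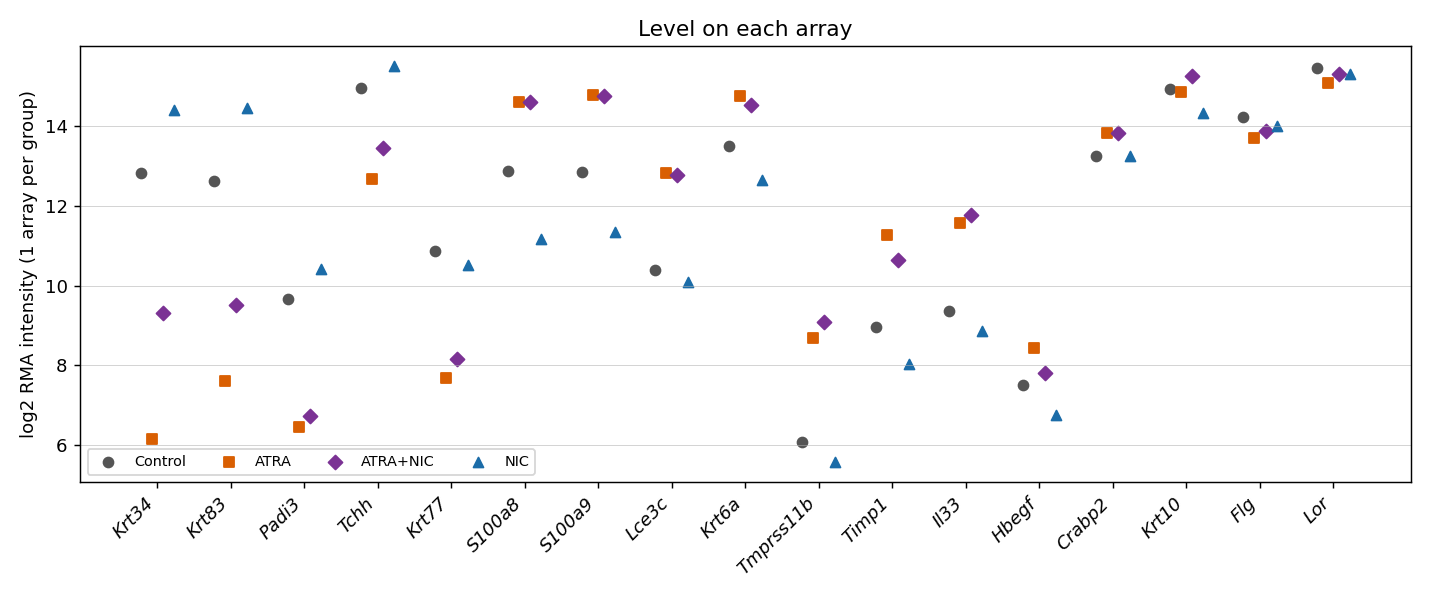
Log2 intensity of named genes on each of the 4 arrays, 1 point per array. Krt34 read 12.81 on Control, 6.15 on ATRA, 9.30 on ATRA+NIC and 14.39 on NIC, while Lor lay between 15.06 and 15.46.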

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

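The test on hair list members outside the Krtap family was chosen only after the hair result was seen, as was the stricter reading of the growth-phase test given below, and a count related to the bright-symbol test had been seen before it.

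Hair shaft genes were lower on both ATRA arrays. A shift between arrays shared by genes of like brightness is argued against, since the list lay far below random lists matched on brightness. Cyclic loess removes only such a shift, so the ATRA axis median of -3.63 after it is no further evidence. Cross-hybridisation within the Krtap family is argued against as the whole cause, since the 23 members outside it had a median of -3.07. A candidate explanation is that the follicles were in another stage of the growth cycle. A separate list of 16 measured growth-phase genes had an ATRA axis median of -0.41, at percentile 0 of random lists, which by the rule set beforehand fits that explanation. But ATRA minus Control alone gave -0.040, at percentile 22.3, with 10 members below 0 and 6 above. In ATRA+NIC minus NIC the median was -0.87, with 13 below 0 and 3 above. The members at least 2-fold lower in both were Bambi (-1.76 and -2.79), Vdr (-1.41 and -1.69) and Dsg4 (-1.38 and -2.04). The explanation stays undecided. Mice of all groups have the same age in the labels, so a difference in labelled age is not behind a difference in stage. The hair list had a median log2 level of 12.21 on Control, 13.73 on NIC, 7.99 on ATRA and 9.30 on ATRA+NIC. With 1 array per group, a difference between mice or skin sites cannot be told apart from one due to the cream.

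SPRR, LCE3 and alarmin genes were lower on NIC than on Control, and not on ATRA+NIC than on ATRA. Saturation of bright probes is argued against as the whole cause, since the 12 members under log2 12 on all arrays had an interaction axis median of 0.39, above the middle 95% of random lists. The lists were picked for this pattern, so that percentile is no separate support for the pattern itself. A shift between arrays shared by genes of like brightness is argued against, since the median of all 40 members also lay above random lists matched on brightness. Of these members 33 were above 0 on the interaction axis and 7 below. Their median was 0.39 (0.385) after cyclic loess, which removes only such a shift and is no further evidence. A high Control array or a low NIC array would give the same values as a NIC effect that is absent with ATRA, and 1 array per group leaves that open.

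NIC differences recurred little in the other background, with r = 0.0458 across genes, which are not independent replicates. Noise of dim symbols may be part of the cause, since at or above percentile 75 of brightness 44 symbols were at least 2-fold the same way in both differences and 1 in opposite ways. Most of the 44 were hair or unnamed genes, and without them 5 went the same way and 1 opposite ways. Among the same bright symbols r was still only 0.143 for NIC, against 0.690 for ATRA, so recurrence stays weak without dim symbols, their noise does not account for the whole pattern, and a small or absent NIC effect stays open.

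Several named genes had ATRA differences in opposite directions with and without NIC, on 1 array per group, and the difference was not tested. ATRA+NIC minus NIC and then ATRA minus Control were Fscn3 1.70 and -1.11, Gpr151 1.11 and -2.24, Grip1os1 -1.16 and 2.08, Gzmg 1.15 and -1.21, Mycn -3.18 and 1.20, Rrh -1.56 and 1.05, Septin10 -1.72 and 2.79 and Zbed6 1.13 and -1.47. Each was named for an extreme value of a NIC difference that shares an array with both of these, so opposite directions are partly built in.

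Gene list medians also lay outside the middle 95% of random lists in opposite directions for NIC in both backgrounds. ATRA+NIC minus ATRA and then NIC minus Control were 0.20 and -0.22 for cornified envelope structural proteins, 0.24 and -0.81 for SPRR and LCE3 precursors and 0.21 and -0.44 for aquaporins and hydration. The interaction axis, 0.5 times the difference of both, had medians of 0.22, 0.68 and 0.29 for these lists, at percentiles 100, 100 and 99.8 of random lists. The lists were picked for opposite medians in these same differences, so high percentiles on this axis follow from the choice and are no separate support. Against a spread between replicates the difference was not tested, as each group has 1 array. Mycn, a MYC family transcription factor, was at -3.17 and 1.21 in the same comparisons, at least 2-fold in opposite directions, and the difference was not tested.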

How the results depend on the processing

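All alternatives here were planned except the counts without hair and Krtap genes, which were chosen after seeing the data: they gave 121 and 213 symbols for ATRA and 102 and 73 for NIC in both backgrounds. Of list medians under the alternatives, 1366 stayed within 1 standard deviation of random lists, 176 moved further and 2 that lay outside the middle 95% of random lists changed sign, and of named gene values 3792 stayed within the array noise at their brightness, 6 moved further and 2 that were at least 2-fold apart changed sign. Of the main results, 74 stayed and 81 moved, most of them counts that change because the alternative tests other symbols or another fold, and 1 that lay outside the range of random sets changed sign. Values inside those ranges or under 2-fold that crossed 0 are counted as stayed or moved. The cause was not tested for the others. Array signal over background limits dim genes, since a difference of 2 arrays had to pass 2.18 log2 in the dimmest decile of symbols and 0.75 in the brightest to leave the range of 95% of interaction values. At or above percentile 75 of brightness the share of 2-fold symbols that were higher went from 42.9% to 31.0% in ATRA minus Control, from 54.0% to 86.0% in ATRA+NIC minus ATRA, from 43.1% to 29.3% on the ATRA axis, from 55.8% to 84.4% on the NIC axis and from 56.3% to 80.6% on the interaction axis, and at 3-fold it was 24.5% and 66.9% on the ATRA and NIC axes. The sign changes counted were Dsg2 with the brightest target, from -1.26 and -1.14 in ATRA minus Control and NIC minus Control, the junction list at or above percentile 75 of brightness, from -0.25 in ATRA+NIC minus NIC and -0.17 on the interaction axis, and the symbols higher with ATRA in the deposited value table, from 0.096 in ATRA+NIC minus ATRA. The symbols lower with ATRA also crossed 0 with the brightest target, from 0.019 in ATRA+NIC minus ATRA, which lay inside the range of random sets. Values below are counts of symbols at least 2-fold apart unless named as medians of a list or set or as a gene's log2 difference. With no filter on dim genes the values were ATRA minus Control 2418, NIC minus Control 2730, ATRA+NIC minus Control 3133, ATRA+NIC minus ATRA 2563, ATRA+NIC minus NIC 3389, NIC axis 1098, NIC in both, lower 130, limma ATRA rises 8, hair shaft and inner root sheath (other cell type): median ATRA axis -3.48, hair shaft and inner root sheath (other cell type): median NIC axis 0.80, ATRA-responsive symbols (higher): median interaction axis 0.19, ATRA-responsive symbols (lower): median interaction axis -0.19. At or above percentile 75 of brightness the values were ATRA minus Control 252, NIC minus Control 265, ATRA+NIC minus Control 311, ATRA+NIC minus ATRA 107, ATRA+NIC minus NIC 437, ATRA axis 225, NIC axis 77, interaction axis 31, ATRA in both, higher 27, ATRA in both, lower 130, NIC in both, higher 43, NIC in both, lower 1, limma ATRA rises 29, limma ATRA falls 134, limma NIC rises 27, tight and adherens junctions and desmosomes: median ATRA+NIC minus NIC 0.081, tight and adherens junctions and desmosomes: median interaction axis 0.0034, hyperproliferation keratins and alarmins: median ATRA axis 1.00, hair shaft and inner root sheath (other cell type): median ATRA axis -3.94, hair shaft and inner root sheath (other cell type): median NIC axis 1.27, ATRA-responsive symbols (higher): median ATRA+NIC minus ATRA 0.0066, ATRA-responsive symbols (higher): median interaction axis 0.40, ATRA-responsive symbols (lower): median ATRA+NIC minus ATRA 0.67, ATRA-responsive symbols (lower): median interaction axis -0.056. With the brightest target of each symbol the values were NIC minus Control 2352, ATRA+NIC minus ATRA 2066, NIC axis 1110, interaction axis 1023, NIC in both, lower 133, limma ATRA rises 0, hair shaft and inner root sheath (other cell type): median NIC axis 1.05, ATRA-responsive symbols (lower): median ATRA+NIC minus ATRA -0.037, Dsg2, ATRA minus Control 0.52, Dsg2, NIC minus Control 1.03. With the deposited value table the values were ATRA+NIC minus ATRA 778, ATRA axis 600, NIC axis 294, interaction axis 263, NIC in both, higher 64, NIC in both, lower 23, limma ATRA rises 27, limma ATRA falls 145, ATRA-responsive symbols (higher): median ATRA+NIC minus ATRA -0.032. At 1.5-fold the values were ATRA minus Control 3677, NIC minus Control 4182, ATRA+NIC minus Control 4317, ATRA+NIC minus ATRA 3273, ATRA+NIC minus NIC 4776, ATRA axis 2917, NIC axis 2244, interaction axis 2148, ATRA in both, higher 525, ATRA in both, lower 602, NIC in both, higher 364, NIC in both, lower 336. At 3-fold the values were ATRA minus Control 512, NIC minus Control 473, ATRA+NIC minus Control 681, ATRA+NIC minus ATRA 540, ATRA+NIC minus NIC 818, ATRA axis 318, NIC axis 163, interaction axis 98, ATRA in both, higher 27, ATRA in both, lower 145, NIC in both, higher 31, NIC in both, lower 12. With cyclic loess the values were limma ATRA rises 0, hair shaft and inner root sheath (other cell type): median ATRA axis -3.63, ATRA-responsive symbols (higher): median ATRA+NIC minus ATRA 0.16, ATRA-responsive symbols (lower): median ATRA+NIC minus ATRA 0.047. With each array centred on its median the values were limma ATRA rises 0, ATRA-responsive symbols (higher): median interaction axis 0.21. With an intensity trend in eBayes the values were limma ATRA rises 185, limma ATRA falls 307, limma NIC rises 93, limma NIC falls 32. At an unadjusted p under 0.05 the values were limma ATRA rises 544, limma ATRA falls 644, limma NIC rises 400, limma NIC falls 367.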

Other observations

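Other cell type and stress lists moved little or went different ways with ATRA. On the ATRA axis the medians were 0.18 for oxidative stress and NRF2 targets, 0.10 for interferon response, 0.090 for heat shock and unfolded protein response (mean of the opposite sign), 0.062 for immediate early genes (mean of the opposite sign), -0.060 for sebocytes, 0.043 for adipocytes, 0.16 for skeletal muscle, 0.029 for fibroblasts (mean of the opposite sign), -0.049 for T, NK and B cells, -0.073 for red blood cells and -0.13 for nerve and Schwann cells. Single genes were farther apart. Slc7a11, a cystine transporter of the NRF2 response, differed by 1.15 and 3.06, with a reading of 54.2 on NIC, under 2 times the random probes, and Gsta4, a glutathione transferase, by 1.23 and 1.66, while Chac1, which degrades glutathione, differed by -1.92 and -2.93 and was the 1 heat shock list member that fell when adjusted over the list alone, with 0 over all genes. Lrrc15, a gene of the fibroblast list, differed by -1.53 and -3.61. In tight and adherens junctions and desmosomes the ATRA axis median was -0.074, with Dsg3 at 0.85 and 1.32, in aquaporins 0.094, in basal keratinocyte genes 0.10 with Krt15 at -0.69 and -2.20, and in NAD metabolism 0.17.

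The 43 symbols at least 2-fold higher with NIC in both backgrounds at or above percentile 75 of brightness were all at least 2-fold lower with ATRA in both. Over all kept symbols 54 of the 129 higher with NIC in both were, 27 of them hair list or Krtap genes. Both sets rest on the same 4 arrays, so this overlap is not independent evidence. The bright named genes outside the hair list and Krtap family were Car6, Dapl1, Gprc5d and Ly6g6d, chosen after their values were seen, at 2.01 and 1.86 for Car6.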
